A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

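Gene expression was measured by RNA sequencing in 4 strains of the yeast Saccharomyces cerevisiae fermenting a synthetic grape must. Each strain and SO2 level is represented by 1 library, so no group has a replicate. Per the labels' protocols, ribosomal RNA was removed from total RNA and whole transcriptome libraries were made for the SOLiD 4 sequencer. The deposited values are RPKM, reads scaled by gene length and by the mapped reads of the library, per the file headers. The aligner, the counting tool, the genome build and the gene models behind the RPKM are not given in the sources used here.

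The deposited table held 6611 rows and 1 RPKM column for each of the 6 libraries. Of these rows, 6534 carried an identifier of the Saccharomyces Genome Database and 77 did not, and 6039 had a value in all 6 libraries. The 8 rows that shared 4 systematic names were left out, and 2 genes were read from the end of another line. Genes without a value were the same in both VL3 libraries and the same in both AWRI796 libraries, so having a value went by strain. Of the rows with such an identifier, 100 had a value in only R008 and EC1118 or in only VL3 and AWRI796, against 28 and 12 for the other ways of pairing the 4 strains. Gene lengths used per strain are not given in the sources used here. A comparison between strains therefore mixes expression with gene models and mapping. Within VL3 or AWRI796 the same genes had a value, though reads shared between near-identical copies could still affect a change. Coordinates are those of the deposited table: start and end equalled those of the R64 annotation for 5868 of the 5877 genes found in both.

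Depth is unknown, because RPKM hold no counts. Low values were checked for whole multiples of 1 read, using gene lengths from the coordinates. At the step that served each library best, between 27.6% and 32.3% of low values lay within 0.1 of a whole read, against 20% for a single step by chance, so reads were not recovered. No counting interval or detection floor is given, and a 0 is described only as listed at 0. RPKM summed to between 778099 in R008 with SO2 and 1070965 in AWRI796 with SO2.

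RPKM were divided by 1 median-of-ratios factor per library, computed from 4993 genes and ranging from 0.88 to 1.153. Values are given as scaled RPKM. Changes were taken on log2(scaled RPKM + 1), so fold changes stand on the scale with a pseudocount of 1 and understate the change of genes with low values. Genes with a mean deposited RPKM of at least 5 were kept, which left 5335. Within VL3 and within AWRI796, sizes of change are given without a test, since 1 library per group has no replicate check. Over both strains, limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with trend) was fitted to 4 libraries with strain as a block, which leaves 1 residual degree of freedom. The same fit gave AWRI796 against VL3. A second fit set R008 against the 3 enological strains with SO2, with 2 residual degrees of freedom, and assumed that the single R008 library varies like these. Tests were two-sided with Benjamini-Hochberg adjustment at 0.05. Nothing in the labels says that libraries of different strains are replicates of one condition, so adjusted p-values rest on the spread between these strains or SO2 levels. That spread is largely pooled over genes by eBayes. The pooled part had 6.44 degrees of freedom against 1 residual in the first fit, and 8.54 against 2 in the second. An SE therefore says little about the spread of its own gene.

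Gene lists were fixed before the data were examined: 33 of them, of which 30 had at least 3 measured members. Over a fit they were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation. The estimated version rests on the residual degrees of freedom, 1 or 2 here, so it could hardly call any list. Within a strain, the median of a list was placed among 10000 random lists of the same size, drawn within 20 bins of mean expression. Named genes followed a rule fixed at the same time: SSU1 and FZF1 in every library; the 10 highest and 10 lowest mean changes among genes moved at least 1.5-fold alike in both strains; the 5 highest and 5 lowest in each strain; the 10 highest and 10 lowest of each strain comparison; the 3 widest gaps per strain and direction; and up to 4 members per list. Dubious reading frames and genes with a near-identical copy were passed over or named as uncertain, and of the rest the text names only a part; 1 of them is not reported here. Near-identical copies were found with BLAST+ 2.17.0 on coding sequences of R64, as at least 95% identity over at least 80% of the gene, in 222 genes.

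The fits were tested on simulated data with 200 changed genes. Noise was drawn independently for each gene from the spread that eBayes pools over genes, so the assumptions of the fits were built in. The shares below describe such data and not the measured libraries. There STL1, with a mean log2 change of 3.67 in the SO2 comparison, was not called (limma adjusted p = 0.14). In the SO2 comparison of 5092 genes, 10.4% of genes changed by 1 on the log2 scale were called, 80.6% of those changed by 2 and 95.5% of those changed by 3, with 9 false calls among 133. For AWRI796 against VL3, over 5092 genes, the shares were 7.5%, 89.6% and 98.5%, with 11 false calls among 141. For R008, over 5009 genes, they were 1.5%, 52.2% and 95.5%, with 4 false calls among 103. Alternatives were pseudocounts of 0.1 and 5, no filter, a minimum of 20, RPKM as deposited, quantile normalization, fits without blocks or trend, and leaving out libraries. Leaving out dubious reading frames and rows with shared values, and camera in the strain comparisons, were added after seeing the data. Scripts also used Python 3.11.15, pandas 2.3.3, Biopython 1.88 and matplotlib 3.10.9.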

Results

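Transcript levels were compared in 4 wine strains of Saccharomyces cerevisiae growing in MS300, a synthetic medium made to resemble white grape must, at the time when 6 g/l of CO2 had been released. SO2, the preservative of winemaking, was added at 25 mg/l or left out. VL3 and AWRI796, both enological strains, were measured without and with SO2. EC1118, a further enological strain, and R008, a vineyard strain, were measured with SO2, and their cultures without SO2 were not analysed here. Each of the 6 libraries stands alone in its group. The depth of the libraries is unknown. All levels are scaled RPKM, and all fold changes are on the log2(scaled RPKM + 1) scale, with SO2 against without unless another comparison is named.

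SSU1 (YPL092W, chromosome 16, 373793 to 375169, R64) encodes the plasma membrane pump that exports sulfite. In AWRI796 it stood at 11.1 without SO2 and 552 with SO2, a difference of 45.7-fold. In VL3 its level was 817 without SO2 and 709.5 with SO2, so that SSU1 was also high in the culture without SO2. With SO2, EC1118 reached 949 and R008 reached 2982, the highest of the 4 strains. FZF1 (YGL254W, chromosome 7, 22304 to 23203), the transcription factor that activates SSU1, lay between 10.3 and 17.9 in all 6 libraries. None of these differences within a strain has a replicate check. Over both strains the SSU1 change was 2.66 ± 1.1 on the log2 scale (SE, limma adjusted p = 0.66). That SE is largely pooled over genes and understates the distance between the strains, at -0.2 in VL3 and 5.51 in AWRI796.

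**Figure D1:**
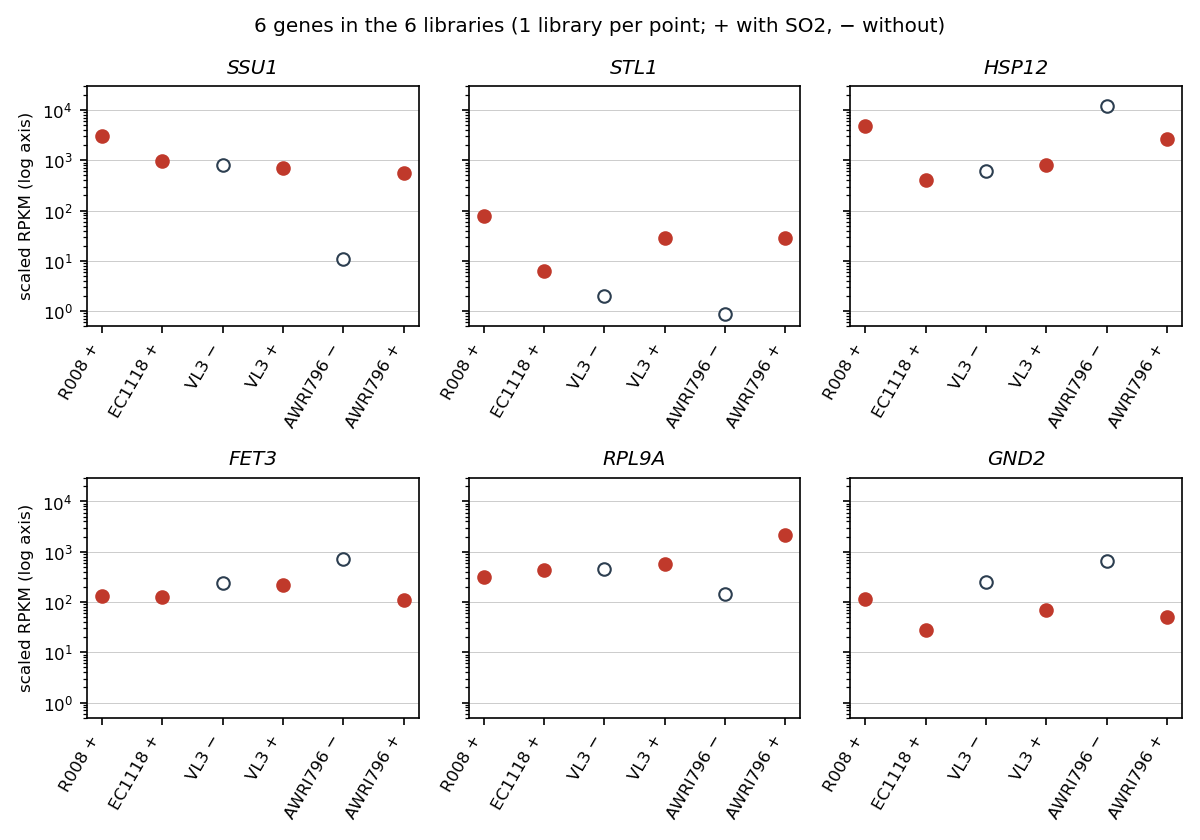
Scaled RPKM on a log axis for 6 genes in the 6 libraries, with 1 point per library; filled points are cultures with SO2 and open points cultures without. SSU1 stands at 11.1 in AWRI796 without SO2 and between 552 and 2982 in the other 5 libraries.

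In VL3, 159 genes were at least 2-fold higher with SO2 and 117 at least 2-fold lower, of 5150 compared. At a pseudocount of 1, the largest increase among genes without a near-identical copy was in STL1, a glycerol and proton symporter, from 1.96 to 28.8 (10.1-fold). MCM16, a kinetochore protein gene listed at 0 without SO2, stood at 5.15 with SO2, a log2 change of 2.62 that became 5.71 at a pseudocount of 0.1, past the 3.81 of STL1. YMR244W was 6.04-fold higher, PRM7 5.11-fold higher and ROX1, a repressor of hypoxic genes, 4.81-fold higher. Among the lowest, leaving out dubious reading frames, were YMR118C at 10.6-fold, YET2 at 5.5-fold, RTA1 at 4.68-fold, IRC4 at 4.63-fold and SGA1 at 4.56-fold. Without the scaling factors the median gene shifted by 0.15 on the log2 scale, and the split became 248 higher and 71 lower. A pseudocount of 5 left 176 genes and a minimum mean of 20 left 181, and without a filter 198 were higher and 213 lower.

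In VL3, genes of the cell surface, of sterol synthesis and of respiration stood higher with SO2 than most random lists. The anaerobic mannoprotein list had a median log2 change of 0.67, with 10 of 17 members at least 1.5-fold higher, above the random lists (percentile 100), against 0.04 in AWRI796 (percentile 34.9), which was -0.03 without the scaling factors. Its members PAU3, PAU19, PAU13 and PAU7 have near-identical copies and are uncertain. For ergosterol synthesis the median was 0.33 (percentile 99.7) and in AWRI796 -0.13 (percentile 4.2), with HMG1, a rate-limiting step of the pathway, 4.11-fold higher, ERG20 2.26-fold and ERG25 2.1-fold. The respiratory chain list had a median of 0.4 (percentile 100), with CYC7, a cytochrome c isoform, 3.06-fold higher, and of -0.19 in AWRI796 (percentile 4.1). Nitrogen catabolite repressed genes went the other way, at a median of -0.75 (percentile 0) and in AWRI796 of -0.35 (percentile 1.4), and 10 of 19 in VL3 were at least 1.5-fold lower, among them DUR3 and GDH2. Multidrug and weak acid exporters had a median of -0.42 (percentile 0.3), with TPO4 2.48-fold lower and PDR10 2.23-fold lower, and of -0.33 in AWRI796 (percentile 1.7). Oxidative stress genes had a median of 0.16 (percentile 95.8).

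In AWRI796 the changes were more numerous: 402 genes at least 2-fold higher and 318 at least 2-fold lower, of 5158, which is 2.61 times as many as in VL3. Without the scaling factors the split was 352 higher and 359 lower. Among genes without a near-identical copy, the highest after SSU1 at a pseudocount of 1 were YMR244W at 31.3-fold, RTA1, a gene of a lipid-translocating exporter family, at 24.7-fold, YOL014W at 23.8-fold and STL1 at 16-fold. Their order rests on the pseudocount: at 0.1 YMR244W had a log2 change of 7.27, RTA1 5.66 and SSU1 5.62, and at 5 SSU1 had 5.11, YOL014W 4.42, RTA1 3.02 and YMR244W 2.93. Among the lowest such genes were COS10 at 23.4-fold, ARN2, a siderophore transporter, at 20.4-fold, BDH2 at 16.2-fold, COS12 at 14.8-fold and PMA2 at 13-fold. COS10 and COS12 belong to a family of subtelomeric genes. Whether AWRI796 responded more strongly than VL3 was not tested.

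Cytosolic ribosomal protein genes were higher in AWRI796 with SO2 almost throughout, 127 of 134 by at least 1.5-fold, with a median log2 change of 1.67 (percentile 100). Their median log2 level was 8.96 in AWRI796 with SO2, outside the 7.35 to 8.36 of the other 5 libraries, and that of stationary phase markers was 6.66 in AWRI796 without SO2 and 6.09 with it. RPL9A went from 142 to 2181, RPS26B from 164 to 881 and RPL5 from 61.6 to 291. RPL9A has a copy, RPL9B, whose coding sequence is 93.8% identical. In VL3, 34 of 136 reached 1.5-fold, and the median was 0.34 (percentile 100). Ribosome biogenesis genes had a median of 0.48 in AWRI796 (percentile 100) and 0.26 in VL3 (percentile 100), with NOP1 2.98-fold and NOP58 2.59-fold higher in AWRI796. Purine and one-carbon synthesis had a median of 0.67 in AWRI796 (percentile 100), led by SHM2 at 6.11-fold and ADE17 at 3.74-fold, and of -0.04 in VL3 (percentile 41), which was 0.13 without the scaling factors. The branched-chain, histidine and aromatic amino acid list had a median of 0.48 in AWRI796 (percentile 99.4), with GCN4, the activator of amino acid synthesis, 3.06-fold higher, and of -0.08 in VL3 (percentile 20.7), which was 0.09 without the scaling factors.

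Most iron regulon genes were lower in AWRI796 with SO2, and stress genes went both ways. Of 25 iron regulon genes, 22 were at least 1.5-fold lower, at a median of -1.1 (percentile 0), among them the iron oxidase FET3 at 6.33-fold and its partner permease FTR1 at 4.86-fold. In VL3 the median of that list was -0.11 (percentile 20.8), which was 0.04 without the scaling factors. General stress and heat shock genes had a median of -0.44 (percentile 0), with 14 of 32 at least 1.5-fold lower and 5 at least 1.5-fold higher, whereas in VL3 the median was 0.29 (percentile 99.9). HSP26 was 6.39-fold and HSP12 4.63-fold lower, GRE1 3.95-fold higher, and SSA2, uncertain for its near-identical copy, 5.68-fold higher. Oxidative stress genes had a median of -0.52 (percentile 0), 13 of 31 at least 1.5-fold lower and 3 higher, with the glutaredoxin GRX1 5.05-fold lower. Markers of stationary phase moved with these groups: their median log2 level was 6.66 in AWRI796 without SO2 and between 5.44 and 6.09 in the other 5 libraries. The iron regulon stood at 8 in that library against 6.27 to 7.13 in the others, and HSP12 at 12049 against 409.5 to 4737. HSP12, GRE1 and SSA3 belong to both the stationary phase and the general stress lists, and CTT1 to both the stationary phase and the oxidative stress lists. The stationary phase markers are therefore not independent of these stress lists.

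**Figure D2:**
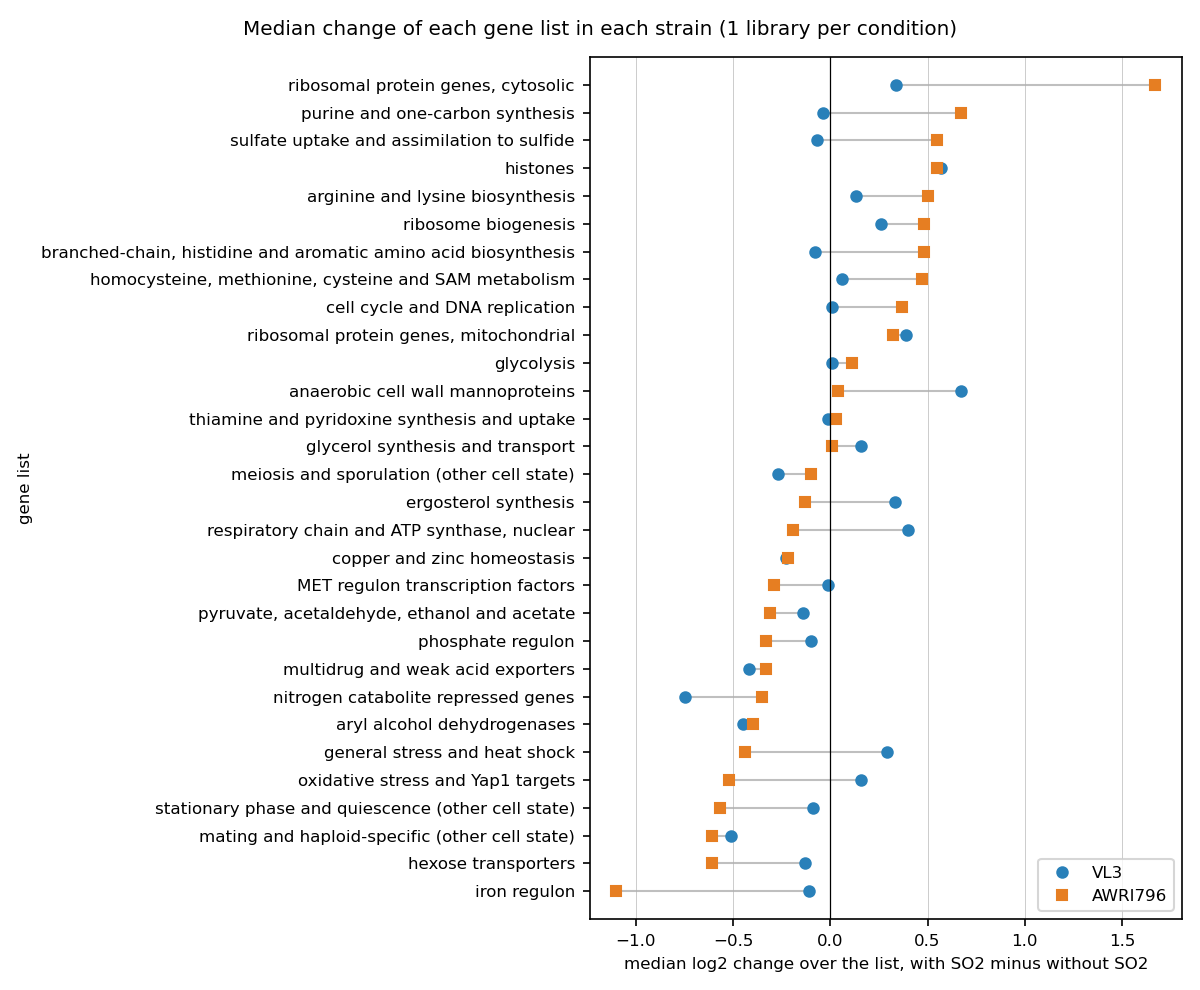
Median log2 change with SO2 minus without, over the members of each gene list, in VL3 (circles) and AWRI796 (squares), from 1 library per condition. Cytosolic ribosomal protein genes lie at 0.34 in VL3 and 1.67 in AWRI796, and the iron regulon at -0.11 (0.04 without the scaling factors) and -1.1.

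Genes of sulfate assimilation, a pathway with sulfite as an intermediate, had a median log2 change of -0.07 in VL3 (percentile 28.8) and 0.55 in AWRI796 (percentile 92), and the VL3 median was 0.1 without the scaling factors. No member reached 1.5-fold in VL3, and 5 of 10 were at least 1.5-fold higher in AWRI796, led by MET14 at 2.76-fold and MET22 at 2.29-fold. Methionine, cysteine and SAM genes had medians of 0.06 (percentile 74.4) and 0.47 (percentile 98.8). HOM3, which opens the pathway from aspartate, was 1.98-fold higher in VL3 and 1.95-fold higher in AWRI796. MET regulon transcription factors had medians of -0.01 (percentile 56.2; 0.16 without the scaling factors) and -0.29 (percentile 12.7). Of other lists tied to sulfite, the pyruvate, acetaldehyde, ethanol and acetate list had medians of -0.14 (percentile 11.3) and -0.31 (percentile 1.4), and thiamine and pyridoxine genes -0.01 (percentile 48.7) and 0.03 (percentile 46.4). These 2 VL3 medians were 0.03 and 0.16 without the scaling factors, and the thiamine median in AWRI796 was -0.04. Median changes of the remaining lists, in VL3 and then in AWRI796, were 0.13 (percentile 90.3) and 0.5 (percentile 99.2) for arginine and lysine synthesis, 0.01 (percentile 56.8) and 0.37 (percentile 99.5) for cell cycle and DNA replication, and 0.01 (percentile 40.6) and 0.11 (percentile 35.9) for glycolysis. They were 0.16 (percentile 84) and 0.01 (percentile 46.4) for glycerol, -0.13 (percentile 23.9) and -0.61 (percentile 3.2) for hexose transporters, -0.1 (percentile 35.1) and -0.33 (percentile 4.6) for the phosphate regulon, and -0.23 (percentile 8.8) and -0.22 (percentile 10.8) for copper and zinc. Without the scaling factors the hexose and phosphate medians in VL3 were 0.03 and 0.07, and the glycerol median in AWRI796 was -0.05; with quantile normalization the glycolysis median in AWRI796 was -0.06. Mating genes stood at -0.51 and -0.61 and meiosis genes at -0.27 and -0.1, each over 3 members, and aryl alcohol dehydrogenases at -0.45 (percentile 9.4) and -0.4 (percentile 10).

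Both strains shared part of their changes. At least 1.5-fold higher in both were 145 genes, where independent lists of these sizes would share 94.9, and at least 1.5-fold lower in both were 144, against 75.4. Genes that went apart numbered 75 and 85, against 82.5 and 86.7. Across 5092 genes, which are not independent replicates, the changes in the 2 strains had r = 0.13 and rho = 0.12. Among the highest in both were YMR244W, STL1, YOL014W, PHO84, PRM7, GRE1, RPS26B, RPL5 and NDE1. STL1 had a mean log2 change of 3.67 ± 0.41 (SE, limma adjusted p = 0.14), PHO84, the phosphate transporter, 2.45 ± 0.69 (adjusted p = 0.61) and GRE1, a desiccation stress gene, 2.1 ± 0.29 (adjusted p = 0.23). Lowest were YMR118C, GND2, BDH2, RRT1, SPS19, QNQ1, YPS6, YOR381W-A, FOX2 and PDC6. Their mean log2 changes included -2.93 ± 0.47 for YMR118C (adjusted p = 0.27), -2.76 ± 0.46 for GND2, of the pentose phosphate pathway (adjusted p = 0.27), and -1.92 ± 0.39 for FOX2, of peroxisomal fatty acid oxidation (adjusted p = 0.45). SPS19, of the same process, overlaps another reading frame and is uncertain. No gene passed limma's threshold among 5092, while 375 had an unadjusted p under 0.05, where chance gives 255. Without the scaling factors, 200 genes were higher and 88 lower in both. At pseudocounts of 0.1 and 5 the mean log2 change was 4.59 and 1.02 for PHO84 (1.71 with quantile normalization), 4.35 and 2.41 for STL1, and -3.59 and -1.76 for YMR118C.

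**Figure D3:**
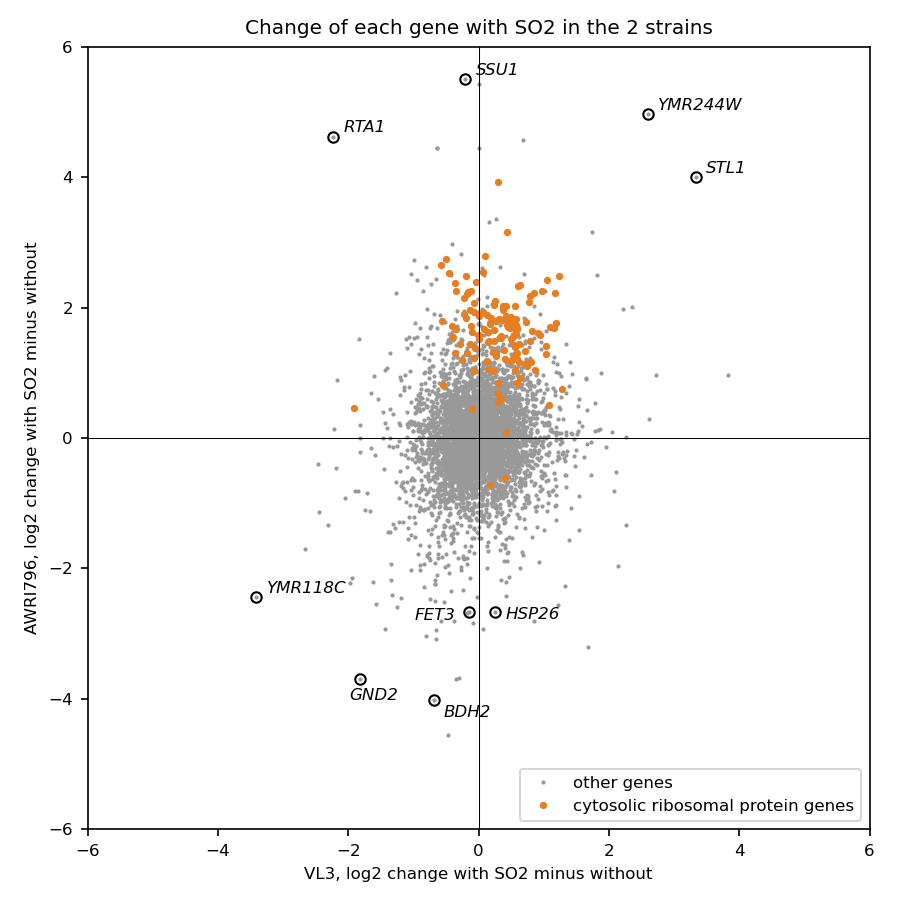
Log2 change with SO2 minus without for each gene in VL3 (horizontal) and AWRI796 (vertical), 1 point per gene, with cytosolic ribosomal protein genes in colour and 9 genes circled. STL1 and YMR244W lie high in both strains, and SSU1 lies at -0.2 in VL3 and 5.51 in AWRI796.

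Over both strains, 11 lists passed limma's camera test at the preset correlation, 8 higher and 3 lower. Higher were cytosolic ribosomal proteins (adjusted p = 2.88e-40), mitochondrial ribosomal proteins (6.84e-07), ribosome biogenesis (8.81e-07), histones (6.8e-04), cell cycle and DNA replication (0.0017), purines (0.00893), arginine and lysine synthesis (0.00902) and the branched-chain list (0.0259). Lower were the iron regulon (5.29e-05), nitrogen catabolite repressed genes (0.00121) and multidrug exporters (0.0259). Some of these calls rest mainly on AWRI796. Medians in VL3 and AWRI796 were -0.11 and -1.1 for the iron regulon and -0.04 and 0.67 for purines. They were -0.08 and 0.48 for the branched-chain list, and 0.01 and 0.37 for cell cycle and DNA replication. None of them held with an estimated correlation, where limma's lowest adjusted p was 0.752 over the lists. With 1 residual degree of freedom that version could hardly call any list, so it decides nothing. Mitochondrial ribosomal proteins lost their call though their estimated correlation, -0.0117, lay below the preset 0.01. For cytosolic ribosomal proteins it was 0.854, far above the preset, so their p at the preset correlation may be too small. Mitochondrial ribosomal protein genes had medians of 0.39 in VL3 (percentile 100) and 0.32 in AWRI796 (percentile 100). For histones the medians were 0.57 (percentile 99.9) and 0.55 (percentile 92.8), with HTB2 1.94-fold and 2.77-fold higher. Adjusted over the list alone, 4 of 14 multidrug exporters were called lower, 2 of 32 general stress genes higher and 2 of 9 glycerol genes higher, against 0 over all genes. Of histones and stationary phase markers, 1 each was called higher in this way, and of the acetaldehyde list and mating genes 1 each lower. This adjustment was made within each list and not across the lists, some of which share members, so these calls are weak.

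Between strains, AWRI796 differed from VL3 over both SO2 levels in 17 genes of 5092 by limma, 8 higher and 9 lower in AWRI796, and 610 had an unadjusted p under 0.05 where chance gives 255. SSS1, a subunit of the translocation channel of the endoplasmic reticulum (YDR086C, chromosome 4, 616928 to 617170), was 2.48 and 2.54 in VL3 and 359 and 499.5 in AWRI796, a log2 difference of 6.92 ± 0.29 (SE, adjusted p = 2.5e-05). By camera, which was run on the strain comparisons only after the data had been seen, 5 lists were higher and 4 lower in AWRI796 at the preset correlation. Stationary phase markers had the lowest p (median 0.96, adjusted p = 0.00105 at the preset correlation). Their median log2 level was 6.66 in AWRI796 and 5.67 in VL3 without SO2, but 6.09 and 5.93 with it. By median level the difference was thus larger in the cultures without SO2. The 0.96, however, is a median of per-gene differences over both SO2 levels, which medians of levels do not split. Single members varied: HSP12 differed mainly without SO2, SPS100 about alike at both levels and FMP45 more with SO2. None of the 9 lists held with an estimated correlation, where the lowest adjusted p was 0.944, but 1 residual degree of freedom leaves that version little chance to call any list. MTC7 was listed at 0 in both VL3 libraries and stood at 45.4 and 66.1 in AWRI796. SEM1, a proteasome subunit, was 11.6-fold higher (adjusted p = 0.0076) and SPS100, a spore wall gene, 5.96-fold higher (adjusted p = 0.011). Lower in AWRI796 were YCL042W (chromosome 3, 50584 to 50943) at -9.37 ± 0.33 (adjusted p = 1.7e-05), the kinase gene RIM15 at -2.88 ± 0.34 (adjusted p = 0.017) and TUS1, an exchange factor for Rho1, at -2.83 ± 0.35 (adjusted p = 0.023). YCL042W overlaps GLK1 (50838 to 52340) in part. Without and with SO2, YCL042W and GLK1 stood at 1586 and 1876, then 919 and 1098, in VL3. In AWRI796 they stood at 0.746 and 1292, then 0.9 and 611. With SO2, SSS1 stood at 257.5 in R008 and 320 in EC1118, so VL3 was the strain apart, and MTC7 had no value in R008. For YCL042W, SSS1 and MTC7, as for other differences between strains, a difference in gene models or mapping cannot be told from one in expression. Below the threshold, HSP12 was 7.89-fold higher and SSU1 9.32-fold lower in AWRI796 (adjusted p = 0.16 and 0.31). Both differences lay mainly in the cultures without SO2. SSU1 was 11.1 in AWRI796 against 817 in VL3 without SO2, and 552 against 709.5 with it. HSP12 was 12050 against 614 without SO2, and 2600 against 818 with it. Of the 17 genes, 9 have a near-identical copy, are dubious or overlap another gene, and are uncertain, such as CUP1-1 and CUP1-2, which carry identical values in VL3. Without a filter on low values no gene was called. RIM15 and TUS1 lost their calls without the scaling factors and with quantile normalization, and SEM1 with quantile normalization and without the SO2 term.

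R008, the vineyard strain, differed from the 3 enological strains with SO2 in 9 genes of 5009, 2 higher and 7 lower, and 158 had an unadjusted p under 0.05 where chance gives 250. PGU1, the endopolygalacturonase that degrades pectin (YJR153W, chromosome 10, 722815 to 723900), stood at 53 in R008 and between 0.349 and 2.09 in the others, a log2 difference of 4.68 ± 0.7 (SE, limma adjusted p = 0.023). ECM34 was lower, at 5.29 against 183 to 1772 (-6.99 ± 0.99, adjusted p = 0.019), as was MAS1, a subunit of the mitochondrial processing protease, at 17.2 against 77.6 to 95.4 (-2.26 ± 0.33, adjusted p = 0.023). The 183 for ECM34 was in EC1118, against 1772 in VL3 and 1545 in AWRI796. ECM34 thus also parted R008 and EC1118 from the other strains. PDC5, a pyruvate decarboxylase, was 11.9-fold higher, HSP12 4.96-fold and SSU1 4.14-fold, none past the threshold (adjusted p = 0.12, 1 and 0.35). RPL11A, TEF2, RPL4A, RPS4B and SSA2 were also called lower, and each has a near-identical copy, while the other gene called higher, YPR002C-A, is a dubious reading frame. TEF2 stood at 0.341 and its copy TEF1 at 768 in R008. Camera was also run on the lists, but R008 is 1 library, so only median log2 differences are given, for the lists that camera picked at the preset correlation. They were -0.64 for cytosolic ribosomal proteins, -0.42 for ribosome biogenesis, -0.6 for purines, -0.51 for arginine and lysine synthesis and -0.26 for the branched-chain list. Above 0 among the lists picked were general stress (0.58), respiratory chain (0.27), oxidative stress (0.24), aryl alcohol dehydrogenases (0.62), MET regulators (0.47) and the acetaldehyde list (0.08). Lists not picked lay on both sides of 0, such as thiamine and pyridoxine genes at 0.29 and histones at -0.2. By median log2 level, general stress genes did not set R008 apart, at 8.18 in R008, 8.38 in VL3, 8 in EC1118 and 7.76 in AWRI796. This is another measure than the 0.58, which is a median of per-gene differences, so it does not set that value aside. For cytosolic ribosomal proteins the median log2 level was 7.82 in R008, 8.09 in VL3, 8.36 in EC1118 and 8.96 in AWRI796. The limma test of single genes takes the single R008 library to vary like the 3 others. PGU1 kept its call in 5 of 11 alternatives that tested it, with adjusted p up to 0.4, ECM34 and MAS1 in 7 of 12 each, and the higher calls ran from 0, as in the fit over all 6 libraries with an SO2 term (3 lower), to 6; without a filter no gene was called.

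With SO2, each strain had genes at least 4-fold away from all 3 others. R008 had 5 above and 9 below, EC1118 5 and 2, VL3 3 and 6, and AWRI796 6 and 8, of 5009, with no replicate check. Over the 4 strains this was 19 above and 25 below, and the latter became 35 at a pseudocount of 0.1, 14 at 5 and 16 with a minimum mean of 20. All these counts include genes with near-identical copies or shared values and dubious reading frames. With those left out, only ECM34 and MAS1 stayed 4-fold below in R008, as the next gene, HUG1, had a gap of 3.71-fold. In VL3 only GFD2 stayed 4-fold above, and the next gene, YEH1, had a gap of 2.66-fold. In EC1118, PTR2, a peptide transporter, was 156 against at most 12.2, and CTR3, a copper transporter, 39.9 against at most 3.79. IRC7, a cysteine desulfhydrase gene, was 7.36 in EC1118 against at least 135. In VL3, GFD2 was 151 against at most 32.1, and ACS1, an acetyl-CoA synthetase, 0.986 against at least 13.1. In AWRI796, RTA1 was 41.4 against at most 5.6, SPS100 114 against at most 17, and YJR120W was listed at 0 against at least 12. In R008, PDC5 was 2502 against at most 358, and YMR175W-A 105 against at most 21.1.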

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

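No difference in this part was tested. General stress and heat shock genes went apart in the 2 strains: with SO2 their median log2 change was 0.29 in VL3 and -0.44 in AWRI796, a difference of -0.73. This difference, and those of the genes that follow, rest on 1 library per condition. They were picked because VL3 and AWRI796 went opposite ways, and 25 of the 76 genes that changed at least 2-fold in both strains did so. Such genes were not unusually common: at 1.5-fold, 75 and 85 genes went apart, where independent lists would give 82.5 and 86.7. RTA1 differed by 6.85 on the log2 scale, at -2.23 in VL3 and 4.63 in AWRI796. The stress gene DDR2 differed by -3.6, at 1.33 and -2.28, and the heme oxygenase gene HMX1 by -4.11, at 2.15 and -1.96. CTR3 differed by -3.59, at 2.26 and -1.33. ICL2 differed by 3.36, at -1.84 and 1.52, YDR034W-B by 3.5, at -1.27 and 2.23, KSH1 by 2.66, at -1.35 and 1.31, and the cyclin gene PCL1 by 2.07, at -1.05 and 1.03.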

How the results depend on the processing

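Leaving out dubious reading frames and rows with shared values, and camera in the strain comparisons, were chosen after the data were seen; the first moved no total by over 1.5 times, and the higher calls in R008 from 2 to 1. The count of 2-fold changed genes in VL3, 276, was 176 with a pseudocount of 5 and 181 with a minimum mean of 20, which tests fewer genes. Without a filter, AWRI796 against VL3 went from 17 genes to 0 and R008 against the enological strains from 9 to 0. The R008 comparison, 2 higher and 7 lower, gave 0 and 7 with a pseudocount of 0.1, 0 and 3 over all 6 libraries with an SO2 term, 1 and 7 without EC1118, and 6 and 7 without VL3 or without AWRI796. The 11 lists called by camera were 0 with an estimated correlation, a version that could hardly call any list with 1 residual degree of freedom. Unless stated here, the cause was not tested. The SO2 response over both strains stayed at 0 genes in the blocked fit under every alternative, in the fits with no replicate block over 4 libraries and over 6, and without trend. A blocked fit with a library left out has no residual degree of freedom, so these were run without strain: they gave 0 to 2 genes, the 2 without the VL3 library without SO2. No paired analysis by replicate number was possible because each group holds 1 library. Of 465 values of named genes under alternatives, 400 lay within 1.5-fold of the value given, 1 of them with the other sign, and 65 differed by more in size with the same sign. Depth is unknown and limits what low genes show.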

Other observations

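Of the tests in this part, those of scaling, of rows with a value by pairs of strains, of a loss alike in SSU1 and its neighbours, and the second version of the test on gene copies were chosen after a result was seen.

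Nitric oxide dioxygenase, encoded by YHB1, stood at 393 in R008 and 673 in EC1118 with SO2, against 15.7 in VL3 and 11.6 in AWRI796. YCT1, a cysteine transporter, was 434 and 400 against 118 and 169. SPR3, a sporulation septin, went the other way, at 0.284 and 1.29 against 31.6 and 34.8, as did HOP2, a meiotic gene, at 0.455 and 0.418 against 8.63 and 14.5. These genes were chosen after their values were seen. Separate handling of these 2 pairs of strains, as a hypothesis, would part more genes by this pairing than by others. It parted 17 genes by at least 2-fold, 0.81 times the 21 of R008 and VL3 against EC1118 and AWRI796, and the third pairing parted 7. In number this met the outcome set beforehand against separate handling, no more genes than the higher of the other pairings. The 17 were 44.7% of both (exact binomial 95% interval 28.6% to 61.7%). That interval takes genes as independent, which genes measured in 1 library per strain are not, so the gap has no replicate check. Rows with a value on only one side were 3.57 times as many for this pairing as for the next, 100 against 28. Among them YLR154C-G, an open reading frame within the ribosomal DNA, was at 56995 to 68351 RPKM as deposited in the VL3 and AWRI796 libraries and had no value in R008 and EC1118. Gene models or libraries handled apart and relatedness of the strains cannot be told apart here, since either would give this.

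Among the 77 rows without an identifier of the Saccharomyces Genome Database, R008 had a value in 32, 8 at 100 RPKM or more, led by R008_J1_0006 at 4786 and R008_E1_1731 at 4509 as deposited. EC1118 had 47, 2 of them shared with R008, and 4 reached 100, among them a row described as a nicotinic acid permease of Zygosaccharomyces rouxii type at 115.

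SSU1 was far lower in AWRI796 without SO2 than in any other library. Scaling does not account for it, since the smallest log2 change over 3 scalings was 5.37. A loss of reads around the gene was tested on the 2 genes on each side: their median change was 1.06, between the bounds set beforehand, so that test decided nothing, and 1 of the 4 is itself a ribosomal protein gene. A loss alike in SSU1 and its neighbours is argued against, since SSU1 exceeded the highest of them by 4 on the log2 scale. Induction by SO2 may explain the rest, as an untested hypothesis from 1 library per condition, and so may another difference between the 2 cultures, since stationary phase markers stood at 6.66 in that library against 5.44 to 6.09 in the others; repeat cultures would part these.

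Ribosomal protein genes were higher in AWRI796 with SO2 than without. Gene length and GC content are argued against: each gene's change was set against the median of the 50 other genes nearest to it, and the median excess over the 134 genes was 1.58 for length and 1.67 for GC content. A difference between the 2 cultures other than SO2, such as their growth state, cannot be told apart from a response to SO2: the library with SO2 lay 0.6 above the range of the other 5, which either could give. Stationary phase markers, at a median log2 level of 6.66 in the library without SO2, belong to the same open question. A response to SO2 stays possible and was not tested against it.

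Copies of some duplicated ribosomal protein genes moved apart in AWRI796, such as RPL41A at 3.17 and RPL41B at -0.72, with coding sequences 98.7% identical. Reads shared between near-identical copies could do this. Over 56 of the 59 pairs, identity and the distance between the changes had rho = 0.04 (permutation p = 0.76, two-sided; r = 0.18), which decides nothing. A first version of the test aligned whole genes with introns and covered only 16 pairs, where rho was 0.61 (permutation p = 0.014); it was replaced, with that result known, because it covered too few pairs. Without the 2 pairs farthest from the median identity, rho over all pairs was 0.01.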
